A study of Mus musculus with 8 samples.

How the data were processed

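The series measured total RNA of mouse cells on 8 arrays, from 100 ng of RNA each: 1 of MEFs, 2 of episomal iHeps, 2 of viral iHeps and 3 of primary hepatocytes. Groups were taken from the labels, and the hepatocyte array without a number in its title is called hepatocyte 3. The deposited values are log2 intensities per probe set. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes between arrays and summarizes probes, and with Partek; versions, and whether all arrays were normalized together, are not given in the sources used here. The log2 scale was checked on the values, and no values were transformed. Arrays whose sorted values differed by a mean of less than 0.05 were joined into distribution sets, which gave 3 sets. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

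Of 45141 probe sets, 104 controls were left out. An annotation table held 29449 of them, 28898 with 1 gene symbol and 551 with several, which were not used; 15588 probe sets had no name there. Entrez identifiers of 28689 were found in the mouse gene table and 0 symbols needed an update. For the 7180 genes with several probe sets the one with the highest mean over all arrays was kept, which left 17097 genes, with no filter on dim genes. Where other probe sets of a called gene point the other way, which holds for 12 of 642 pairs of a named gene and a comparison, the text says so for the genes it gives with their statistics.

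Groups were compared in limma with lmFit and eBayes, 1 mean per group over all 8 arrays, so that every group shares 1 estimate of the spread per gene (4 residual degrees of freedom, prior degrees of freedom 3.78, median posterior SD 0.34). The single MEF array is thereby assumed to vary like the other groups. A gene is called, and said to rise or fall, at a Benjamini-Hochberg adjusted two-sided p under 0.05 within a comparison. The 7 comparisons are hepatocytes, episomal iHeps and viral iHeps against the MEF array, each kind of iHep and their mean against hepatocytes, and episomal against viral iHeps. Differences are first group minus second. Shares of hepatocyte-like changes have exact Clopper-Pearson intervals and stand beside simulations of unchanged iHeps.

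The lists were fixed before the data were examined, as were the comparisons, tests, named-gene rule and most of the other settings. They hold the 3 vector factors, 12 marker genes, and 24 tested lists: liver transcription factors, plasma proteins, xenobiotic enzymes, urea cycle and amino acid, glucose, bile acid and transporter, lipid, epithelial, bile duct, fibroblast, positional, cell cycle, fetal liver and imprinted, gut, macrophage, endothelial, stellate and mesothelial, blood cell, pluripotency, interferon-stimulated, acute phase and inflammatory, YAP and TGF-beta, p53 and senescence, and glycolysis and hypoxia genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists of a comparison, and again with an estimated correlation. That estimate takes in the higher level of hepatocyte 3, not co-variation alone. The text draws named genes from the factors and markers, from the 5 largest called increases and decreases per comparison among genes whose arrays do not overlap between the groups, and from up to 4 called members of each list (or up to 2 uncalled ones, as values). Among these, genes whose call held when each array was left out were preferred after their values were seen.

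The settings chosen before were an intensity trend in eBayes, quantile and cyclic loess normalization, a filter at the median level, the mean of all probe sets, an added 2-fold threshold, a fit of the compared groups alone, leaving out each replicate in turn, the replicate number as a block, and the estimated correlation for lists. Pairing by replicate number was checked. A random block for the distribution set (duplicateCorrelation), a fit within 1 set, and leaving out both hepatocyte 3 and viral iHep 2 were chosen after seeing the data. The fit was tested on simulated independent genes, 100 changed per step. A log2 change of 3 was recovered in 87, 97 and 94 of 100 genes (episomal iHeps against the MEF array, hepatocytes and viral iHeps). A change of 1 gave 0, 4 and 3, with 7, 4 and 4 false calls among 17097 genes. A shift of 56 plasma protein genes by 1 gave camera an adjusted p of 7.96e-19, and 0 other lists were called. False calls with correlated genes or between sets were not tested. Computation used R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.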

Results

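Messenger RNA was measured on 8 expression arrays of mouse cells, all from C57Bl/6 mice. Induced hepatocytes (iHeps) are hepatocyte-like cells converted directly from mouse embryonic fibroblasts (MEFs) with the transcription factors Gata4, Hnf1a and Foxa3. The factors came from episomal vectors, which do not integrate into the genome, in 2 arrays and from a viral vector in another 2. The MEFs (1 array, embryonic day 13.5) were the negative control, and cultured primary hepatocytes of adult male mice (3 arrays, culture day 6) were the positive control. Medians of the deposited log2 values over probe sets were 4.24 in the MEF array, 4.14 in each episomal array and 4.13 in each viral array. Hepatocytes 1, 2 and 3 had medians of 4.23, 4.24 and 5.06. Sorted values fell into 3 sets of arrays: the MEF array with hepatocytes 1 and 2, the 4 iHep arrays, and hepatocyte 3. The mean gap between sorted values was 0.0073 to 0.0164 within a set and 0.1244 to 0.7314 between sets, so iHeps are compared with both controls across separately distributed arrays. The number of arrays limits the precision.

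**Figure D1:**
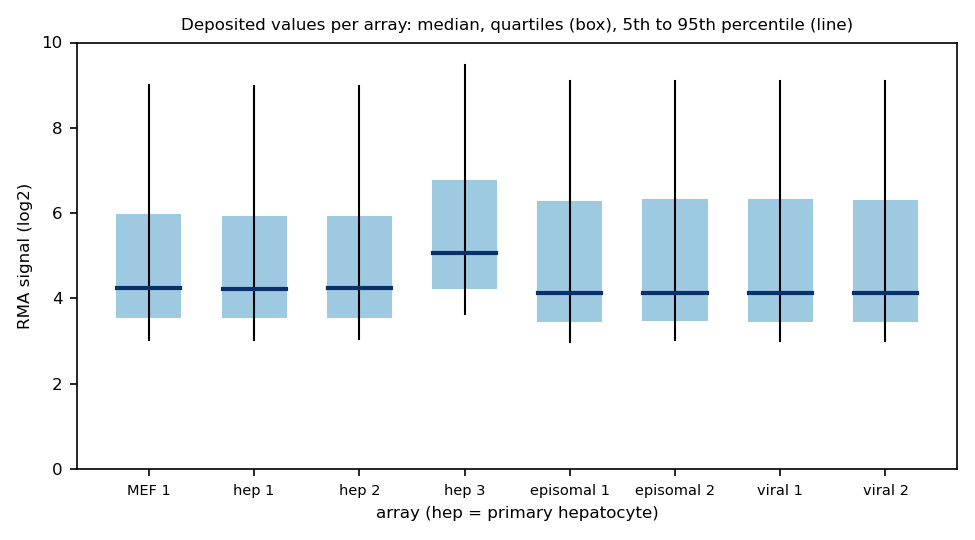
Deposited log2 values of each array (x axis, 8 arrays) on the y axis, with the median, quartiles and the range from the 5th to the 95th percentile over probe sets. Hepatocyte 3 has a median of 5.06 and the other 7 arrays have medians from 4.13 to 4.24.

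The vector factors were read first. Gata4 was not called in any comparison. It was 4.12 in the MEF array, 3.99 ± 0.06 in episomal iHeps, 3.99 ± 0.05 in viral iHeps and 4.77 ± 0.53 in hepatocytes (mean ± SD, log2). Foxa3 was 3.71 in the MEF array, 3.77 ± 0.07 in episomal and 3.69 ± 0.08 in viral iHeps, and 6.40 ± 0.21 in hepatocytes. Hnf1a has no named probe set and was not analysed here. A probe set outside the part of a gene that a vector carries does not read the vector, and where these probe sets lie was not examined. The values of Gata4 and Foxa3 therefore check neither the labels nor the vectors.

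The 12 fixed markers were read in each group. Albumin (Alb), the main plasma protein of hepatocytes, was 4.12 in the MEF array, 7.82 ± 0.28 in episomal iHeps (n = 2), 3.75 ± 0.02 in viral iHeps (n = 2) and 11.90 ± 0.04 in hepatocytes (n = 3). Hnf4a, a nuclear receptor that drives hepatocyte genes, was 5.65, 9.83 ± 0.07, 9.27 ± 0.53 and 9.60 ± 0.16 in the same order. Transthyretin (Ttr) was 3.17 in the MEF array, 12.01 ± 0.02 in episomal iHeps, 11.21 and 3.26 in viral iHeps 1 and 2, and 11.88, 11.71 and 12.41 in hepatocytes. Afp, a secreted protein of fetal liver, was 3.05 in the MEF array, 12.07 ± 0.07 in episomal iHeps, 7.27 and 2.62 in viral iHeps 1 and 2, and 10.10 ± 0.15 in hepatocytes. The urea cycle enzyme Cps1 was 4.71 in the MEF array, 4.05 ± 0.01 in episomal and 4.17 ± 0.13 in viral iHeps, and 7.05 ± 1.00 in hepatocytes. Cyp3a11, a drug-metabolizing enzyme, was 4.66, 3.88 ± 0.25 and 3.98 ± 0.31 in the first 3 groups and 4.83, 5.03 and 8.63 in hepatocytes 1, 2 and 3. The epithelial cadherin Cdh1 was 3.28 in the MEF array, 10.18 ± 0.05 in episomal and 9.08 ± 0.49 in viral iHeps, and 9.27 ± 0.35 in hepatocytes. The keratin Krt18 was 3.80, 10.80 ± 0.04, 10.31 ± 1.00 and 11.85 ± 0.35. The fibroblast genes Col1a1 and Thy1 were 10.00 and 10.67 in the MEF array and at most 3.98 in the other 7 arrays. Vim was 12.07 in the MEF array, 11.63 and 11.62 in episomal iHeps, 11.84 ± 0.28 in viral iHeps and 12.06 ± 0.22 in hepatocytes. The proliferation marker Mki67 was 8.35, 9.36 ± 0.16, 9.49 ± 0.61 and 7.93 ± 0.60.

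**Figure D2:**
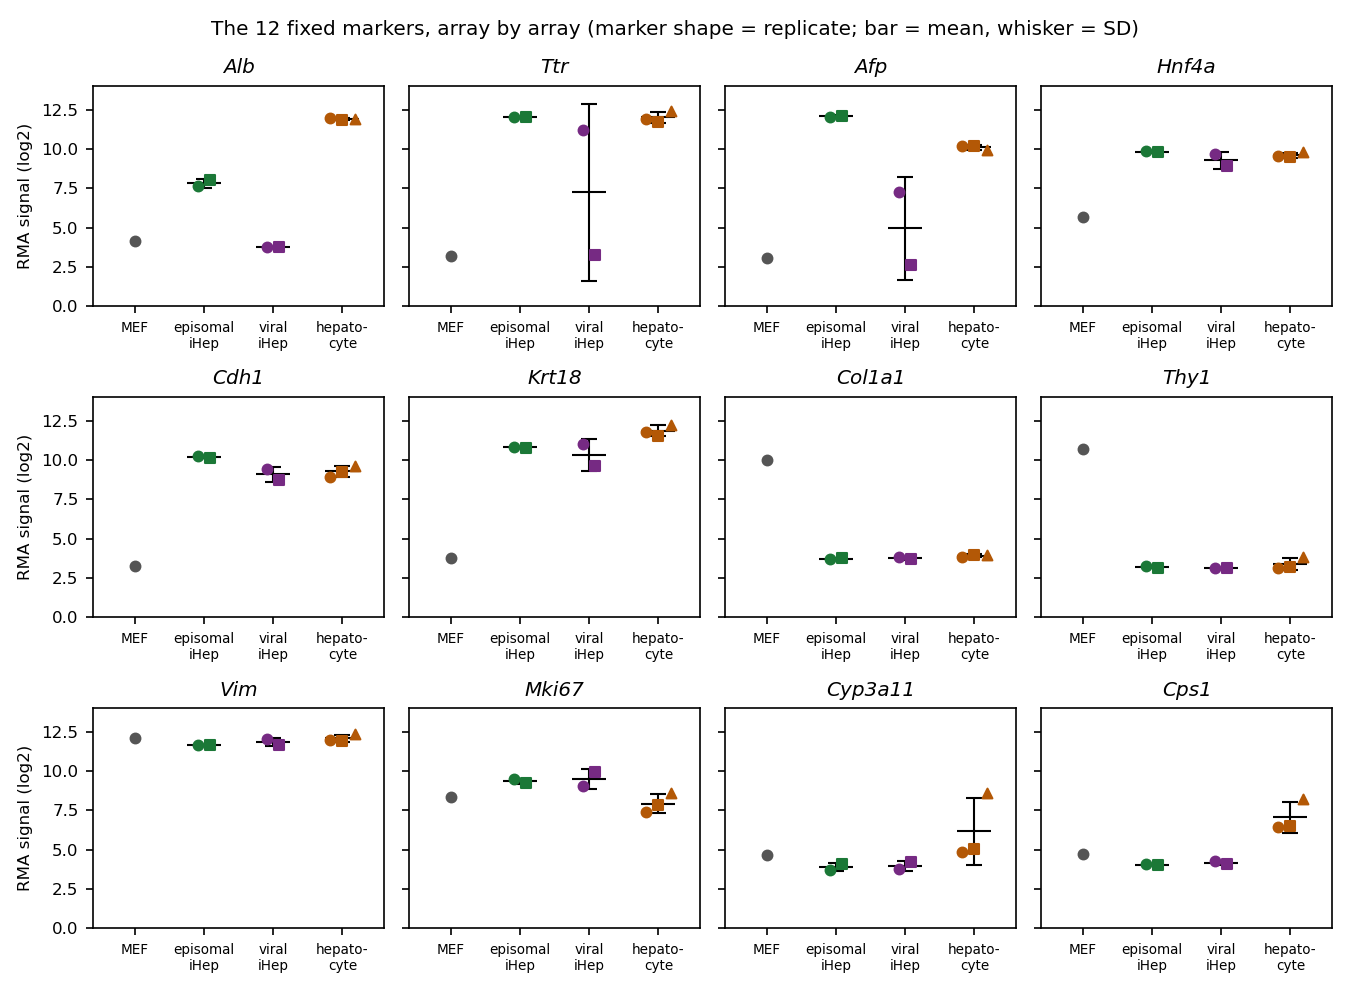
Deposited log2 values of the 12 fixed marker genes (y axis) by group (x axis), 1 point per array with the mean and SD of groups with several arrays. Alb is 4.12 in the MEF array and 11.87 to 11.94 in hepatocytes, and Ttr and Afp differ widely between the 2 viral arrays.

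Primary hepatocytes were compared with the MEF array to define what separates the control cell types. Called higher in hepatocytes were 27 of 56 plasma proteins and 18 of 45 epithelial genes, and called lower were 28 of 45 fibroblast and 12 of 31 interferon-stimulated genes. As lists these had an adjusted p of 0.0457, 0.403, 0.0228 and 0.0457 with an estimated correlation. Alb rose by 7.52 ± 0.29 (adjusted p = 4e-05), where ± gives the SE and the p is from limma. Fibrinogen (Fgb) rose by 8.73, α1-antitrypsin (Serpina1a) rose by 7.74, and retinaldehyde dehydrogenase (Aldh1a1) rose by 7.72. The keratins Krt18 (7.79) and Krt8 (7.47) rose as well. The matrix protease Mmp3 fell by 8.06, and Cdh11 (-8.01), Crabp1 (-7.74), Thy1 (-7.54) and Mgp (-7.47) also fell. In all, 380 genes were called higher and 421 lower. The median difference over all genes was 0.263 (hepatocytes higher), largely from hepatocyte 3. Differences of this comparison are therefore given relative to that median. Those of iHeps against hepatocytes are given relative to medians of -0.23 (episomal), -0.228 (viral) and -0.226 (all iHeps). The calls test the unshifted differences. The count of 801 genes was 527 without either episomal array. Without hepatocyte 3 it was 2291 (1135 higher and 1156 lower), with 750 of the 801 among them. With the distribution set as a random block 2663 genes were called, and after another quantile normalization 1597. Within the set that holds the MEF array and hepatocytes 1 and 2, 6174 genes were called (3263 higher and 2911 lower).

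Of 56 plasma proteins, 27 rose and 0 fell (42 and 0 within the list, adjusting over its genes alone), as in Ambp (7.42). Of 24 liver transcription factors, 10 rose and 0 fell (14 and 1 within the list), as in Foxa1 (4.03), Hnf4a (3.69) and Onecut1 (3.09). The vector factor Foxa3 rose by 2.42. Of 57 xenobiotic enzymes, 10 rose and 0 fell (13 and 0 within the list), as in Ugt2b35 (5.76) and Ugt2b34 (5.20). Of 45 epithelial genes, 18 rose and 0 fell (20 and 0 within the list), as in Dsg2 (6.89), Cldn2 (6.37), Perp (6.28) and Cdh1 (5.72). Camera, limma's test of a list against all other genes, gave these 4 lists adjusted p-values of 8.2e-36, 4.19e-09, 4.72e-08 and 3.54e-15, and 0.0457, 0.192, 0.503 and 0.403 with an estimated correlation. Of 45 fibroblast genes, 0 rose and 28 fell (0 and 34 within the list), as in Lum (-6.81), Postn (-6.80) and Col1a1 (-6.35). Of 31 interferon-stimulated genes, 0 rose and 12 fell (0 and 26 within the list), as in Cxcl10 (-6.71), Oasl2 (-5.40) and Ifit3 (-5.38). The adjusted p-values of both lists were 1.14e-55 and 8.2e-36, and 0.0228 and 0.0457 with an estimated correlation. Positional genes are the Hox and related genes of trunk and limb mesenchyme. Of 48 positional genes, 0 rose and 8 fell (0 and 8 within the list), as in Hoxa10 (-4.58), Shox2 (-4.32) and Tbx18 (-3.53). Of 13 fetal liver and imprinted genes, 1 rose and 4 fell (1 and 9 within the list), as in Meg3 (-5.20), Igf2bp3 (-3.30) and Ndn (-3.11). Afp of the same list rose by 6.78. Of 21 glycolysis and hypoxia genes, 0 rose and 2 fell (0 and 3 within the list), as in Pkm (-2.54). Of 25 macrophage genes, 1 rose and 2 fell (1 and 4 within the list), as in Lyz2 (-4.07). All 4 lists were lower, with adjusted p-values of 1.22e-09, 3.08e-11, 4.61e-11 and 0.0165, and 0.507, 0.0228, 0.403 and 0.851 with an estimated correlation. Of 20 YAP and TGF-beta targets, 0 rose and 2 fell (0 and 3 within the list), as in Ltbp2 (-5.25). Of 44 cell cycle genes, 0 rose and 0 fell (0 and 0 within the list). Their largest differences were Tpx2 (-1.64) and Cenpa (-1.54), not called. Of 37 urea cycle and amino acid genes, 2 rose and 1 fell (7 and 1 within the list), as in Gldc (4.45) and Oat (-2.35). The first 2 of these 3 lists were lower and the last higher, with adjusted p-values of 0.0287, 1.26e-07 and 0.00167, and 0.851, 0.705 and 0.851 with an estimated correlation. Afp lost its call without hepatocyte 1, 2 or 3 (adjusted p of 0.0513 to 0.0839). Gldc lost its call without hepatocyte 3 (adjusted p = 0.0712). The YAP list lost the call without hepatocyte 3 (adjusted p = 0.404).

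The remaining 11 lists were not called between hepatocytes and the MEF array, with adjusted p-values from 0.0728 to 0.783. Of 18 glucose genes, 2 rose and 0 fell (4 and 0 within the list), as in Fbp1 (3.34) and Pygl (2.97). Of 32 bile acid and transporter genes, 2 rose and 0 fell (3 and 1 within the list), as in Abcc3 (3.83) and Abcc2 (3.39). Of 37 lipid genes, 3 rose and 3 fell (10 and 5 within the list), as in Acox2 (3.24) and Mttp (2.44), and Fads2 (-2.26). Of 20 bile duct genes, 2 rose and 1 fell (6 and 1 within the list), as in Aqp1 (-3.27). Of 31 acute phase and inflammatory genes, 7 rose and 4 fell (10 and 5 within the list), as in Fgl1 (5.11) and Il6 (-6.41). Of 22 p53 and senescence genes, 1 rose and 1 fell (1 and 1 within the list), as in Cdkn2a (-4.14). No member was called of the gut, endothelial, stellate and mesothelial, blood cell or pluripotency lists. The list median, mean and test differed in sign for endothelial genes (0.01, -0.02 and higher) and acute phase and inflammatory genes (0.10, 0.23 and lower). The bile acid list gained a call without viral iHep 1 or 2 or hepatocyte 1 (adjusted p of 0.0239, 0.0239 and 0.0326). Quantile and loess normalization ended the call of the YAP list (adjusted p of 0.244 to 0.304). The filter on dim genes ended the call of the macrophage and YAP lists (adjusted p of 0.224 to 0.891), with the direction of the macrophage test turned. Averaging probe sets added a call of the glucose and bile acid lists (adjusted p of 0.03 to 0.0496). A fit of these groups alone ended the call of the macrophage list (adjusted p = 0.0548) and added the bile acid list (0.0161). Leaving out both hepatocyte 3 and viral iHep 2 ended the call of the YAP list (adjusted p = 0.253).

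**Figure D3:**
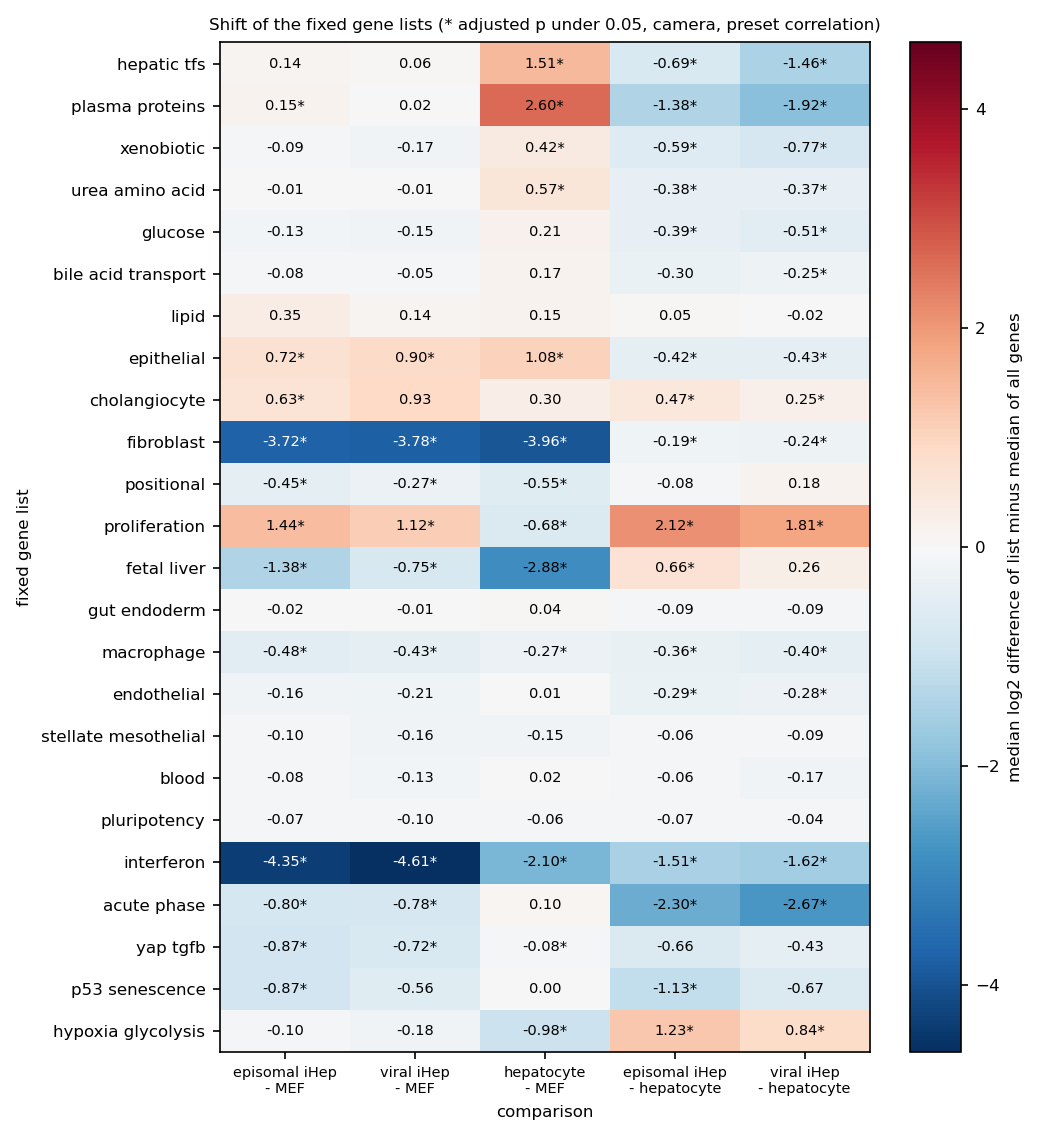
Median log2 difference of each of 24 gene lists (vertical axis) minus the median of all genes in 5 comparisons (horizontal axis), as color, with an asterisk where camera's adjusted p with the preset correlation is under 0.05. Interferon-stimulated and fibroblast genes are lower in both kinds of iHeps than in the MEF array, with medians of -4.35 and -3.72 in episomal iHeps.

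Episomal iHeps were compared with MEFs, their source, whose 1 array cannot separate conversion from a state of that culture. Called lower in episomal iHeps were 31 of 45 fibroblast and 30 of 31 interferon-stimulated genes (28 and 12 in hepatocytes). Called higher were 12 of 56 plasma proteins, 12 of 45 epithelial and 10 of 44 cell cycle genes. With an estimated correlation the adjusted p of these lists was 0.0461, 0.0519, 0.525, 0.643 and 0.525. Afp rose by 9.01 ± 1.47 (adjusted p = 0.0111), and Spink1, a secreted protease inhibitor, by 8.96 ± 0.31 (adjusted p = 3.64e-05). Alb rose by 3.70 ± 0.31 (adjusted p = 0.000465), and Hnf4a by 4.19 ± 0.38 (adjusted p = 0.000647). Bex1 (8.38), Serpina1a (8.37) and Fgb (8.16) rose as well. The collagen Col3a1 fell by 8.83 (adjusted p = 7.33e-05). Ifitm3 (-8.13), Mmp3 (-8.04), Cdh11 (-7.97), Col5a2 (-7.93), Col1a1 (-6.29) and Thy1 (-7.47) fell as well. In limma 432 genes were called higher and 555 lower, assuming that the MEF array varies like the rest. The count of 987 genes was 411 or 412 without episomal iHep 1 or 2. Without hepatocyte 3, an array of neither group, it was 4756 (2759 higher and 1997 lower), with 975 of the 987 genes among them. A fit of only these groups called 7194 (4297 higher and 2897 lower). A random block for the distribution set left 135 genes, and another quantile normalization gave 2254.

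Among the 45 fibroblast genes, 0 rose and 31 fell (0 and 37 within the list), as in Postn (-7.79). Vim was among those not called (-0.45, adjusted p = 0.647). Among the 31 interferon-stimulated genes, 0 rose and 30 fell (0 and 30 within the list), as in Ifit1 (-7.11), Ifit3 (-6.80) and Gbp3 (-6.78). Among the 31 acute phase and inflammatory genes, 0 rose and 6 fell (0 and 8 within the list), as in the chemokines Ccl7 (-7.70) and Ccl2 (-7.56) and the cytokine Il6 (-6.70). For these 3 lists the adjusted p was 4.98e-44, 3.71e-43 and 1.08e-07, and 0.0461, 0.0519 and 0.191 with an estimated correlation. Among the 56 plasma proteins, 12 rose and 0 fell (15 and 1 within the list), as in Serpina1b (7.53) and Apom (7.09). Ttr differed by 8.84 ± 2.50 without a call (adjusted p = 0.0942). Among the 45 epithelial genes, 12 rose and 0 fell (17 and 0 within the list), as in Krt18 (7.0), Cdh1 (6.89), Cldn2 (6.10) and Dsg2 (5.34). Among the 20 bile duct genes, 6 rose and 1 fell (8 and 2 within the list), as in Tspan8 (8.02), Krt19 (6.30) and Itga6 (3.63). Among the 44 cell cycle genes, 10 rose and 0 fell (31 and 0 within the list), as in Bub1 (2.70) and Gins1 (2.35). Mki67 was not called (1.00, adjusted p = 0.429). The adjusted p-values of these 4 lists were 2.94e-05, 5.86e-07, 0.0228 and 4.62e-17, and 0.525, 0.643, 0.525 and 0.525 with an estimated correlation. Bub1 and Gins1 lost their calls without episomal iHep 1 or 2 (adjusted p of 0.0502 to 0.0748). The bile duct list lost the call without hepatocyte 3 (adjusted p = 0.34).

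A further 5 lists were lower in episomal iHeps. Among the 48 positional genes, 0 rose and 5 fell (0 and 6 within the list), as in Shox2 (-3.90) and Tbx18 (-3.28). Among the 25 macrophage genes, 0 rose and 5 fell (0 and 6 within the list), as in Lyz2 (-5.64). Among the 13 fetal liver and imprinted genes, 1 rose and 3 fell (1 and 3 within the list), as in Ndn (-6.27) and Meg3 (-5.82). The rise of that list is Afp. Among the 20 YAP and TGF-beta targets, 0 rose and 2 fell (0 and 2 within the list), as in Ltbp2 (-6.05). Among the 22 p53 and senescence genes, 2 rose and 2 fell (2 and 3 within the list), as in Igfbp3 (-6.27). Their adjusted p-values were 5.63e-06, 4.35e-06, 0.00407, 0.00101 and 0.0228, and 0.643, 0.525, 0.191, 0.643 and 0.853 with an estimated correlation. Among the 24 liver transcription factors, 2 rose and 2 fell (4 and 3 within the list), as in Tbx3 (-3.05). Among the 57 xenobiotic enzymes, 5 rose and 1 fell (5 and 1 within the list), as in Ugt2b34 (5.61), Gsta4 (4.72) and Cyp2d26 (3.80). Among the 37 urea cycle and amino acid genes, 1 rose and 1 fell (3 and 1 within the list). Among the 18 glucose genes, 0 rose and 2 fell (0 and 2 within the list). Among the 32 bile acid and transporter genes, 2 rose and 1 fell (4 and 1 within the list), as in Amacr (2.88). Among the 37 lipid genes, 1 rose and 3 fell (4 and 4 within the list), as in Fads2 (-3.03). Among the 21 glycolysis and hypoxia genes, 2 rose and 0 fell (2 and 0 within the list). Cps1 (-0.66, adjusted p = 0.802) and Cyp3a11 (-0.78, adjusted p = 0.962) were not called. Among the 38 gut genes, 3 rose and 0 fell (3 and 0 within the list), as in the intestinal genes Lgals4 (6.51), Cdx2 (4.92) and Vil1 (3.74). Of the endothelial, stellate and mesothelial, blood cell and pluripotency lists, 1 gene fell, an endothelial one. The 12 lists not called had adjusted p-values from 0.141 to 0.879. Median, mean and test direction differed in sign for xenobiotic enzymes (-0.09, 0.13 and lower), urea cycle and amino acid genes (-0.01, 0.15 and higher), bile acid and transporter genes (-0.08, 0.43 and higher) and gut genes (-0.02, 0.52 and higher). They also differed for stellate and mesothelial genes (-0.10, 0.05 and lower) and glycolysis and hypoxia genes (-0.10, 0.03 and lower). The p53 list lost the call without episomal iHep 2 or hepatocyte 3 (adjusted p of 0.0575 and 0.195) and the fetal liver list without hepatocyte 3 (0.0518). The endothelial list gained a call without hepatocyte 3 (adjusted p = 0.0493). Both quantile and loess normalization ended the call of the bile duct and p53 lists (adjusted p of 0.0689 to 0.198). Filtering out dim genes added a call of the gut list (adjusted p = 0.00808). Omitting both hepatocyte 3 and viral iHep 2 ended the call of the bile duct list (adjusted p = 0.0668).

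Viral iHeps were compared with the MEF array in the same way. Here 29 of 45 fibroblast, 28 of 31 interferon-stimulated and 8 of 31 acute phase and inflammatory genes were called lower, and 7 of 45 epithelial genes and 6 of 56 plasma proteins higher. Their lists had an adjusted p of 0.0404, 0.0429, 0.119, 0.829 and 0.956 with an estimated correlation. Spink1 rose by 8.46 ± 0.31 (adjusted p = 4.08e-05), and Bex1 (8.07), Tspan8 (7.54) and Fgb (7.54) rose as well. The transcription factor Mycn, a proto-oncogene, rose by 7.43, while its 3 probe sets ranged from 0.39 to 7.43. Hnf4a rose by 3.62 ± 0.38 (adjusted p = 0.00149), with 3 of its 4 probe sets in that direction. Alb (-0.37, adjusted p = 0.738), Ttr (4.07, adjusted p = 0.559) and Afp (1.89, adjusted p = 0.691) were not called. Col3a1 fell by 8.57, the interferon-induced chemokine Cxcl10 fell by 7.93, and Mmp3 (-7.93) and Ccl7 (-7.84) fell too. In limma 219 genes were called higher and 450 lower. The 2 viral arrays lay far apart, with 1648 genes at least 2-fold different against 86 between the episomal arrays. The count of 669 genes was 424 without either episomal array. Without hepatocyte 3 it was 4291 (2465 higher and 1826 lower), with 668 of the 669 among them. With only the 3 arrays of these groups in the fit limma called 0 genes, with 3211 at an unadjusted p under 0.05, so every call of this comparison rests on the spread of the other groups too. Without hepatocyte 3 and viral iHep 2, 4539 genes were called higher and 3013 lower. A random block for the distribution set left 130 genes, and the filter on dim genes 392. Another quantile normalization gave 1695.

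Fibroblast genes had 0 rises and 29 falls among 45 (0 and 33 within the list), as in Cdh11 (-7.78), Postn (-7.73), Thy1 (-7.54) and Col1a1 (-6.26). Interferon-stimulated genes had 0 rises and 28 falls among 31 (0 and 30 within the list), as in Ifit1 (-7.01) and Ifit3 (-6.95). Acute phase and inflammatory genes had 0 rises and 8 falls among 31 (0 and 13 within the list), as in Ccl2 (-7.54), Il6 (-6.71) and Saa3 (-5.60). Epithelial genes had 7 rises and 0 falls among 45 (16 and 0 within the list), as in Krt18 (6.51), Cdh1 (5.80), Perp (5.08) and Dsg2 (4.76). Cell cycle genes had 3 rises and 0 falls among 44 (24 and 0 within the list), as in Gins1 (2.39). Those 5 lists had adjusted p-values of 1.78e-47, 1.78e-47, 8.1e-12, 3.35e-07 and 1.92e-14, and 0.0404, 0.0429, 0.119, 0.829 and 0.718 with an estimated correlation. Positional genes had 0 rises and 6 falls among 48 (0 and 6 within the list), as in Shox2 (-3.85) and Tbx18 (-2.06). Macrophage genes had 0 rises and 5 falls among 25 (0 and 6 within the list), as in Lyz2 (-5.60) and Mpeg1 (-2.44). Fetal liver and imprinted genes had 0 rises and 3 falls among 13 (0 and 4 within the list), as in Meg3 (-5.95) and Ndn (-5.71). YAP and TGF-beta targets had 0 rises and 1 fall among 20 (0 and 1 within the list), as in Ltbp2 (-6.01). These 4 lists were lower, with adjusted p-values of 9.99e-05, 5.98e-06, 0.00115 and 0.00787, and 0.847, 0.718, 0.119 and 0.847 with an estimated correlation. The other 15 lists were not called (adjusted p-values from 0.108 to 0.993). Plasma proteins had 6 rises and 0 falls among 56 (6 and 0 within the list), as in Serpina1a (6.73), Serpina1b (6.17) and Rbp4 (5.78). Bile duct genes had 4 rises and 1 fall among 20 (7 and 3 within the list), as in Krt19 (6.25) and Itga6 (3.75), and Aqp1 (-3.78). Liver transcription factors had 1 rise and 2 falls among 24 (1 and 3 within the list), as in Tbx3 (-3.01). Xenobiotic enzymes had 1 rise and 1 fall among 57 (1 and 1 within the list), as in Gsta4 (3.82) and Gstt1 (-3.64). Gut genes had 3 rises and 0 falls among 38 (3 and 0 within the list), as in Lgals4 (5.65) and Cdx2 (4.89). Genes called higher and lower numbered 2 and 1 in the p53 list, 0 and 2 in the glucose, 1 and 1 in the bile acid, 0 and 1 in the lipid and 0 and 1 in the urea cycle list, with Perp higher and Igfbp3 (-5.97), Pygl (-2.81), Cyp7b1 (-3.74) and Angptl4 (-4.90) lower. No gene was called in the glycolysis and hypoxia, endothelial, stellate and mesothelial, blood cell and pluripotency lists. The list median, mean and test differed in sign for liver transcription factors (0.06, 0.07 and lower), urea cycle and amino acid genes (-0.01, 0.14 and higher), bile acid and transporter genes (-0.05, 0.11 and higher) and gut genes (-0.01, 0.57 and higher). The positional list lost the call without viral iHep 1 (adjusted p = 0.131) and the YAP list without viral iHep 2 or hepatocyte 3 (0.441 and 0.0811). The plasma proteins list gained a call without viral iHep 1 or 2 (adjusted p of 0.0111 and 0.0394), the endothelial and p53 lists without viral iHep 1 (0.0452 and 4.65e-06), the bile duct list without viral iHep 2 (0.00417) and the xenobiotic list without hepatocyte 3 (0.0221). The filter on dim genes ended the call of the macrophage list (adjusted p = 0.0902) and added the xenobiotic, bile duct, gut and p53 lists (0.00622 to 0.0471). Averaging probe sets added a call of the bile duct list (adjusted p = 0.0261). A fit of these groups alone ended the call of the YAP list (adjusted p = 0.087) and added the xenobiotic list (0.016). Leaving out both hepatocyte 3 and viral iHep 2 ended the call of the YAP list (adjusted p = 0.428).

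How far iHeps shared the hepatocyte pattern was read from the genes called between hepatocytes and the MEF array. Of the 380 genes higher in hepatocytes, 145 were also called higher in episomal iHeps (38.16%, exact 95% interval 33.25 to 43.25) and 6 lower. In viral iHeps 94 of them were called higher (24.74%, interval 20.48 to 29.39) and 8 lower. Of the 421 genes lower in hepatocytes, 319 were called lower in episomal iHeps (75.77%, interval 71.39 to 79.79) and 3 higher. In viral iHeps 285 of them were called lower (67.7%, interval 63 to 72.14) and 2 higher. Episomal and viral shares were not tested against each other. The intervals treat genes as independent and ignore spread between arrays. All comparisons share the MEF array. As no change was put in, 50 simulations of unchanged iHeps (at most 0.399%) cannot size its part. Independent lists would share 1.281% to 3.246%. Without hepatocyte 3 the shares were 61.94%, 58.06%, 66.61% and 61.94%, over 1135 and 1156 genes. The lowest shares leaving out 1 array were 24.68% and 20% (without episomal iHep 1 or 2), 66.44% (without episomal iHep 2) and 58.13% (without viral iHep 2). With the set as a random block, whose correlation rests on hepatocyte 3 alone, they were 0.8708%, 0.508%, 8.794% and 8.638%. Of the 219 genes higher in viral iHeps than in the MEF array, 174 (79.5%) were among the 432 higher in episomal iHeps. Of the 450 lower ones, 411 (91.3%) were among the 555 lower. Independent lists would share 5.53 and 14.6 genes, and those simulations 0.04 each, with no change put in. The single MEF array cannot be split, so part of this overlap can come from the shared control.

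Arrays were also compared by correlation across genes, which are not independent replicates. The mean Pearson correlation of episomal iHeps was 0.9024 with hepatocytes and 0.852 with the MEF array. That of viral iHeps was 0.8918 and 0.8639, and hepatocytes and the MEF array had 0.8723. Episomal and viral iHeps correlated at 0.9555, the episomal arrays with each other at 0.9949 and the viral arrays with each other at 0.9338. Over genes at or above the median level all values were lower, and that of viral iHeps with hepatocytes lay below that of both controls: episomal iHeps had 0.7382 with hepatocytes and 0.6765 with the MEF array, viral iHeps 0.7211 and 0.7175, and hepatocytes and the MEF array 0.734. These values were not tested.

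Episomal iHeps were compared with primary hepatocytes to see where they differ from the cell type they are meant to resemble. In them 28 of 56 plasma proteins, 10 of 24 liver transcription factors, 15 of 31 acute phase and inflammatory and 18 of 31 interferon-stimulated genes were called lower, and 32 of 44 cell cycle and 5 of 21 glycolysis and hypoxia genes higher. With an estimated correlation no list of this comparison is called, and the adjusted p of these 6 was 0.225, 0.225, 0.225, 0.225, 0.225 and 0.395. Alb fell by 3.85 ± 0.23 (adjusted p = 0.000131) and Aldh1a1 fell by 8.14. The acute phase protein haptoglobin (Hp) fell by 8.09, the glutathione transferase Mgst1 fell by 7.98, and transferrin (Trf) fell by 8.47. Spink1 rose by 8.34 ± 0.23 (adjusted p = 7.94e-06), and Cltrn (7.18), Lgals4 (6.25), Cdkn2a (6.23) and Anxa13 (5.38) rose too. Hnf4a (0.46, adjusted p = 0.636), Ttr (0.24, adjusted p = 0.998), Cdh1 (1.14, adjusted p = 0.15) and Krt18 (-0.82, adjusted p = 0.211) were not called. In limma 496 genes were called higher and 589 lower. Trf lost its call without episomal iHep 1 or 2 or hepatocyte 1, 2 or 3 (adjusted p of 0.0667 to 0.195). The count of 1085 genes was 267 or 268 without episomal iHep 1 or 2, and 629 or 612 without hepatocyte 1 or 2. Without hepatocyte 3 it was 5073 (2807 higher and 2266 lower), with 1040 of the 1085 among them. No distribution set holds both iHeps and hepatocytes. With the set as a random block, whose correlation rests on hepatocyte 3 alone, 5 genes were left. Another quantile normalization gave 2810 genes.

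Among the 56 plasma proteins, 1 rose and 28 fell (3 and 31 within the list), as in Vtn (-6.84), Ambp (-6.62) and Fgg (-6.48). Among the 24 liver transcription factors, 0 rose and 10 fell (0 and 14 within the list), as in Foxa1 (-4.25), Nr5a2 (-2.92), Foxa2 (-2.90) and Onecut1 (-2.85). The vector factor Foxa3 fell by 2.4. Among the 57 xenobiotic enzymes, 2 rose and 11 fell (2 and 16 within the list), as in Ephx2 (-3.77) and Ugt2b5 (-3.68). Among the 31 acute phase and inflammatory genes, 1 rose and 15 fell (1 and 18 within the list), as in Ccl2 (-6.92) and Saa1 (-4.97). Among the 31 interferon-stimulated genes, 0 rose and 18 fell (0 and 27 within the list), as in Usp18 (-5.17) and Rtp4 (-4.33). Adjusted p-values of these 5 lists were 1.51e-13, 3.96e-08, 2.21e-07, 3.96e-08 and 1.86e-14, and 0.225, 0.225, 0.436, 0.225 and 0.225 with an estimated correlation. Among the 44 cell cycle genes, 32 rose and 0 fell (42 and 0 within the list), as in Bub1 (3.56) and Tk1 (2.82). Mki67 was not called (1.66, adjusted p = 0.0906). Among the 21 glycolysis and hypoxia genes, 5 rose and 0 fell (8 and 0 within the list), as in Hk2 (2.63) and Pkm (2.25). Among the 20 bile duct genes, 5 rose and 1 fell (6 and 1 within the list), as in Dmbt1 (3.14). Among the 13 fetal liver and imprinted genes, 2 rose and 1 fell (2 and 2 within the list), as in Igf2bp3 (4.12) and Peg3 (3.92), and Ndn (-3.19). These 4 lists were higher, with adjusted p-values of 2.62e-40, 6.78e-10, 0.00447 and 0.0411, and 0.225, 0.395, 0.371 and 0.32 with an estimated correlation. Among the 37 urea cycle and amino acid genes, 1 rose and 3 fell (1 and 3 within the list), as in Cps1 (-2.77). Among the 18 glucose genes, 0 rose and 3 fell (0 and 4 within the list), as in Pygl (-5.45) and Fbp1 (-3.42). Among the 45 epithelial genes, 1 rose and 10 fell (2 and 14 within the list), as in Perp (-3.74). Among the 45 fibroblast genes, 1 rose and 11 fell (1 and 13 within the list), as in Col5a2 (-2.52) and Col6a1 (3.44). Among the 25 macrophage genes, 0 rose and 3 fell (0 and 6 within the list). Among the 25 endothelial genes, 0 rose and 1 fell (0 and 1 within the list). Among the 22 p53 and senescence genes, 2 rose and 5 fell (2 and 10 within the list), as in Igfbp3 (-4.14). These 7 lists were lower, with adjusted p-values of 0.0155, 0.0155, 0.00447, 0.00331, 0.000444, 0.0259 and 0.0148. With an estimated correlation their adjusted p-values were 0.821, 0.821, 0.821, 0.436, 0.587, 0.821 and 0.805. Foxa1 and Pkm lost their calls without episomal iHep 1 (adjusted p of 0.0527 to 0.0558). Hk2 and Cps1 lost their calls without episomal iHep 1 or 2 (adjusted p of 0.0689 to 0.149). The endothelial list lost the call without episomal iHep 2 or viral iHep 1 or 2 (adjusted p of 0.052, 0.0946 and 0.0946) and the bile duct and fetal liver lists without hepatocyte 3 (0.245 and 0.209).

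The other 8 lists were not called between episomal iHeps and hepatocytes, with adjusted p-values from 0.137 to 0.915. Genes called higher and lower numbered 0 and 5 in the lipid list, 3 and 1 in the bile acid, 2 and 0 in the positional, 3 and 1 in the gut, 1 and 0 in the pluripotency and 1 and 1 in the YAP list, and 0 in the others. Higher were the bile acid enzyme Amacr (2.85), the positional gene Hoxa10 (4.56), and the intestinal genes Cdx2 (4.85) and Vil1 (3.12), and lower Acox2 (-2.74) and Ctse (-1.53) of the lipid and gut lists. Median, mean and test direction differed in sign for lipid genes (0.05, -0.13 and higher), positional genes (-0.08, 0.16 and higher), gut genes (-0.09, 0.33 and higher) and stellate and mesothelial genes (-0.06, 0.22 and higher). They also differed for pluripotency genes (-0.07, 0.04 and lower). Acox2 and Ctse lost their calls without episomal iHep 1 or 2 (adjusted p of 0.0664 to 0.124). The YAP list gained a call without viral iHep 1 or 2 (adjusted p = 0.03) and the bile acid list without hepatocyte 3 (0.0477). Both quantile and loess normalization ended the call of the bile duct and fetal liver lists (adjusted p of 0.0647 to 0.281) and added the YAP list (0.0334 to 0.0423). Loess normalization alone ended the call of the endothelial list (adjusted p = 0.0511). Filtering out dim genes ended the call of the urea cycle, glucose, bile duct, fetal liver and endothelial lists (adjusted p of 0.106 to 0.272) and added the gut list (0.00199). Fitting these groups alone ended the call of the endothelial list (adjusted p = 0.0946) and added the YAP list (0.03). Omitting both hepatocyte 3 and viral iHep 2 ended the call of the glucose, bile duct and fetal liver lists (adjusted p of 0.055 to 0.143) and added the YAP list (0.0197).

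Viral iHeps were set against hepatocytes with the same question. Called lower were 29 of 56 plasma proteins, 11 of 24 liver transcription factors and 16 of 31 interferon-stimulated genes, and called higher 24 of 44 cell cycle and 4 of 21 glycolysis and hypoxia genes. Here too no list is called with an estimated correlation, and the adjusted p of these lists was 0.177, 0.177, 0.177, 0.224 and 0.531. Alb fell by 7.92 ± 0.23 (adjusted p = 7.77e-06), Aldh1a1 fell by 8.00, and Lcn2 (-7.10), Ccl2 (-6.90) and Ambp (-6.89) fell too. Spink1 rose by 7.84 ± 0.23 (adjusted p = 7.77e-06), followed by Mycn (6.89), Mmp13 (6.51), Cdkn2a (5.96) and Eps8 (5.90). Hnf4a (-0.11, adjusted p = 0.517), Cdh1 (0.04, adjusted p = 0.72), Ttr (-4.53, adjusted p = 0.21) and Mki67 (1.79, adjusted p = 0.0736) were not called. In limma 382 genes were called higher and 541 lower. Of the higher genes 275 (72%) were among the 496 higher in episomal iHeps, and of the lower ones 420 (77.6%) among the 589 lower. Independent lists would share 11.1 and 18.6. Simulated iHeps equal to hepatocytes shared 0, as no difference was put in. The count of 923 genes was 517 or 506 without hepatocyte 1 or 2, and 521 without either episomal array. Without hepatocyte 3 it was 5015 (2690 higher and 2325 lower), with 900 of the 923 among them. A random block for the distribution set left 9 genes, and another quantile normalization gave 2600.

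Plasma proteins had 0 rises and 29 falls among 56 (0 and 35 within the list), as in Vtn (-6.74) and Apoe (-6.52). Liver transcription factors had 0 rises and 11 falls among 24 (0 and 14 within the list), as in Foxa1 (-4.30), Foxa2 (-3.13) and Nr5a2 (-3.04). The vector factor Foxa3 fell by 2.48. Xenobiotic enzymes had 0 rises and 15 falls among 57 (0 and 21 within the list), as in Ugt2b35 (-5.93), Gstt1 (-4.93) and Ugt2b34 (-4.53). Acute phase and inflammatory genes had 0 rises and 17 falls among 31 (1 and 20 within the list), as in Hp (-5.90). Interferon-stimulated genes had 0 rises and 16 falls among 31 (0 and 26 within the list), as in Usp18 (-5.35), Rtp4 (-4.01) and Ifi47 (-3.96). These lists were lower, with adjusted p-values of 1.15e-24, 1.31e-10, 3.21e-10, 1.97e-10 and 1.76e-15, and 0.177, 0.177, 0.496, 0.177 and 0.177 with an estimated correlation. Cell cycle genes had 24 rises and 0 falls among 44 (39 and 0 within the list), as in Bub1 (2.82) and Tk1 (2.71). Glycolysis and hypoxia genes had 4 rises and 0 falls among 21 (5 and 0 within the list), as in Hk2 (3.15) and Pkm (2.39). Bile duct genes had 3 rises and 1 fall among 20 (5 and 2 within the list), as in Itga6 (2.64) and Bicc1 (-2.45). These lists were higher, with adjusted p-values of 5.09e-36, 5.52e-08 and 0.0439, and 0.224, 0.531 and 0.578 with an estimated correlation. Urea cycle and amino acid genes had 1 rise and 2 falls among 37 (1 and 5 within the list), as in Oat (2.86). Glucose genes had 0 rises and 2 falls among 18 (0 and 5 within the list), as in Pygl (-5.81) and Fbp1 (-3.83). Bile acid and transporter genes had 1 rise and 2 falls among 32 (1 and 2 within the list), as in Abcc2 (-3.17) and Abcc3 (-2.96). Epithelial genes had 0 rises and 10 falls among 45 (1 and 13 within the list), as in Krt8 (-3.80) and Dsp (-2.73). Fibroblast genes had 2 rises and 8 falls among 45 (3 and 13 within the list), as in Bgn (-2.52), Col5a2 (-2.47) and Fn1 (-2.27). Macrophage genes had 0 rises and 3 falls among 25 (0 and 6 within the list), as in Mpeg1 (-2.05). Endothelial genes had 0 rises and 1 fall among 25 (0 and 1 within the list). These 7 lists were lower, with adjusted p-values of 0.00828, 0.00113, 0.0394, 0.000153, 0.016, 0.000953 and 0.038. With an estimated correlation they were 0.804, 0.666, 0.804, 0.666, 0.591, 0.642 and 0.804. The other 9 lists had adjusted p-values from 0.0614 to 0.876. Genes called higher and lower numbered 2 and 6 in the lipid list, 2 and 2 in the gut, 2 and 0 in the positional, 3 and 2 in the fetal liver, 1 and 0 in the YAP and 1 and 2 in the p53 list, and 0 in the others. They include Lgals4 (5.38), Cdx2 (4.82), Hoxa10 (3.28), Peg3 (3.94), Igf2bp3 (3.80) and Ltbp1 (3.53) on the higher side (2 of 3 probe sets of Ltbp1 in that direction) and Angptl4 (-4.71), Mlxipl (-2.50), Ctse (-1.50), Ndn (-2.63) and Igfbp3 (-3.85) on the lower. The list median, mean and test differed in sign for lipid genes (-0.02, -0.27 and higher), gut genes (-0.09, 0.38 and higher) and stellate and mesothelial genes (-0.09, 0.10 and lower). The bile duct list lost the call without viral iHep 1 or hepatocyte 3 (adjusted p of 0.169 and 0.685), the urea cycle, bile acid and epithelial lists without viral iHep 2 (0.143, 0.189 and 0.112) and the fibroblast and endothelial lists without viral iHep 2 or hepatocyte 1 (0.06 to 0.553). The positional list gained a call without viral iHep 1 or hepatocyte 2 (adjusted p of 3.13e-05 and 0.0414), the fetal liver, YAP and p53 lists without viral iHep 1 (0.0218, 0.00464 and 7.65e-06) and the blood cell list without hepatocyte 3 (0.0257). Quantile and loess normalization ended the call of the bile duct, fibroblast and endothelial lists (adjusted p of 0.0736 to 0.26) and added the positional list (0.0283 to 0.0318). The filter on dim genes ended the call of the urea cycle, bile acid, bile duct and endothelial lists (adjusted p of 0.0741 to 0.166) and added the gut and p53 lists (0.00381 to 0.0174). Averaging probe sets added a call of the positional and fetal liver lists (adjusted p of 0.0154 to 0.0261). Leaving out both hepatocyte 3 and viral iHep 2 ended the call of the bile acid, epithelial, bile duct and endothelial lists (adjusted p of 0.0545 to 0.119).

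The mean of both iHep groups was also set against hepatocytes. Aldh1a1 fell by 8.08 and Alb fell by 5.89 ± 0.19 (adjusted p = 4.39e-06), and Hp (-7.0), Ccl2 (-6.92), Iigp1 (-6.85), Vtn (-6.79), Foxa1 (-4.28), Cps1 (-2.71) and Foxa3 (-2.45) fell as well. Spink1 rose by 8.09 ± 0.19 (adjusted p = 2.64e-06), and Cdkn2a (6.10), Eps8 (5.93), Lgals4 (5.81), Sptssb (5.21) and Cdx2 (4.83) rose. In limma 702 genes were called higher and 938 lower. A total of 12 lists were lower, with adjusted p-values from 1.34e-18 to 0.0302, and from 0.205 to 0.836 with an estimated correlation. Of 56 plasma proteins, 0 rose and 31 fell (0 and 39 within the list). Of 24 liver transcription factors, 0 rose and 12 fell (0 and 17 within the list). Of 57 xenobiotic enzymes, 2 rose and 19 fell (2 and 29 within the list). Of 31 acute phase and inflammatory genes, 1 rose and 17 fell (2 and 20 within the list). Of 31 interferon-stimulated genes, 0 rose and 23 fell (0 and 27 within the list). Of 37 urea cycle and amino acid genes, 1 rose and 4 fell (1 and 6 within the list). Of 18 glucose genes, 0 rose and 4 fell (0 and 5 within the list). Of 45 epithelial genes, 0 rose and 12 fell (2 and 17 within the list). Of 45 fibroblast genes, 1 rose and 12 fell (2 and 15 within the list). Of 25 macrophage genes, 0 rose and 6 fell (0 and 9 within the list). Of 25 endothelial genes, 0 rose and 1 fell (0 and 1 within the list). Of 22 p53 and senescence genes, 2 rose and 4 fell (2 and 8 within the list). Higher lists had adjusted p-values of 2.74e-38, 2.36e-09 and 0.00781, and 0.205, 0.387 and 0.387 with an estimated correlation. Of 44 cell cycle genes, 37 rose and 0 fell (42 and 0 within the list), as in Bub1 (3.19) and Cenpa (3.01). Of 21 glycolysis and hypoxia genes, 6 rose and 0 fell (11 and 1 within the list), as in Hk2 (2.88). Of 20 bile duct genes, 5 rose and 1 fell (7 and 1 within the list). The other 9 lists had adjusted p-values from 0.0819 to 0.82. Genes called higher and lower in them numbered 4 and 8 in the lipid list, 2 and 4 in the bile acid, 2 and 0 in the positional, 3 and 2 in the fetal liver, 3 and 2 in the gut, 1 and 3 in the YAP, 0 and 1 in the blood cell and 1 and 0 in the pluripotency list, and 0 in the stellate list. Median, mean and test direction differed in sign for lipid genes (0.04, -0.20 and higher), gut genes (-0.08, 0.36 and higher), stellate and mesothelial genes (-0.04, 0.16 and lower) and pluripotency genes (-0.08, 0.02 and lower). The endothelial list lost the call without viral iHep 2 (adjusted p = 0.211), the p53 list without hepatocyte 1 or 2 (0.103 and 0.0775) and the bile duct list without hepatocyte 3 (0.425). The positional and YAP lists gained a call without viral iHep 1 (adjusted p of 0.00432 and 0.0123), the fetal liver list without viral iHep 1 or hepatocyte 1 or 2 (0.0223, 0.042 and 0.0436) and the bile acid list without hepatocyte 3 (0.0157). Both quantile and loess normalization ended the call of the bile duct, fibroblast and endothelial lists (adjusted p of 0.0522 to 0.0826). Filtering out dim genes ended the call of the urea cycle, bile duct and endothelial lists (adjusted p of 0.0857 to 0.172) and added the gut list (0.00211). The mean of probe sets added a call of the fetal liver list (adjusted p = 0.0116). Omitting both hepatocyte 3 and viral iHep 2 ended the call of the bile duct list (adjusted p = 0.115) and added the bile acid list (0.0433). The count of 1640 genes was 704 or 686 without episomal iHep 1 or 2, and 874 or 865 without hepatocyte 1 or 2. Without hepatocyte 3 it was 6146 (3270 higher and 2876 lower), with 1592 of the 1640 among them. As a random block the distribution set left 5, and another quantile normalization gave 3878.

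Episomal and viral iHeps were compared to see whether the vector went with a difference. Called higher in episomal iHeps were 4 of 56 plasma proteins (adjusted p = 0.996 for this list with an estimated correlation). Apom, an apolipoprotein, rose by 6.59 ± 0.28 (adjusted p = 0.000159), Alb by 4.07 ± 0.26 (adjusted p = 0.000645), and the complement protein Cfi rose by 6.43. The ribosomal protein gene Rpl39l rose by 6.22. Xist, the RNA that silences an X chromosome in female cells, fell by 4.88 ± 0.30 (adjusted p = 0.000645). Mycn fell by 7.69 and Mgst1 fell by 5.34, but that direction is carried by 1 of 3 probe sets of Mycn and 1 of 2 of Mgst1. Interferon-induced Ifitm3 (-6.34) and Ifitm1 (-5.98) fell. Afp (7.12, adjusted p = 0.0816) and Ttr (4.77, adjusted p = 1) were not called, with the viral arrays far apart. In limma 46 genes were called higher and 18 lower in episomal iHeps. Ifitm3 lost its call without hepatocyte 3 (adjusted p = 0.0518). Ifitm1 lost its call without episomal iHep 1 or 2 or hepatocyte 3 (adjusted p of 0.0521 to 0.07). The count of 64 genes was 16 or 18 without episomal iHep 1 or 2, 346 without viral iHep 1 and 111 without hepatocyte 3. With the distribution set as a random block it was 299, and with only these groups in the fit 21.

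Camera called 6 lists between episomal and viral iHeps at the preset correlation and none with an estimated one (adjusted p = 0.996 for each). Plasma proteins had 4 rises and 0 falls among 56 (4 and 0 within the list), as in Apoh (3.16). Xenobiotic enzymes had 4 rises and 0 falls among 57 (5 and 0 within the list), as in Ugt2b34 (4.91) and Ugt2b35 (3.89). Bile acid and transporter genes had 1 rise and 0 falls among 32 (1 and 0 within the list), as in Amacr (1.85). Cell cycle genes had 0 rises and 0 falls among 44 (0 and 0 within the list). Acute phase and inflammatory genes had 1 rise and 0 falls among 31 (2 and 0 within the list). The p53 and senescence genes had 0 rises and 1 fall among 22 (0 and 1 within the list), as in Perp (-2.51), also an epithelial junction protein. The first 5 lists were higher in episomal iHeps and the last lower, with adjusted p-values of 1.75e-10, 0.00935, 0.0221, 0.000278, 0.00756 and 0.0162 at the preset correlation. The other 18 lists were not called (adjusted p-values from 0.079 to 0.997). Genes called higher and lower in them numbered 1 and 1 in the lipid list, 0 and 1 in the epithelial, 1 and 0 in the bile duct and 1 and 0 in the gut list, and 0 in the others. The list median, mean and test differed in sign for epithelial genes (-0.03, 0.07 and higher), fetal liver and imprinted genes (-0.02, 0.27 and higher) and gut genes (-0.01, -0.05 and higher). Apoh lost its call without episomal iHep 2 (adjusted p = 0.0975). Ugt2b34 lost its call without episomal iHep 1 or 2 (adjusted p of 0.0905 to 0.0962). Ugt2b35 lost its call without episomal iHep 1 (adjusted p = 0.0905). Amacr lost its call without episomal iHep 1 or 2 or viral iHep 1 or 2 or hepatocyte 1 or 2 (adjusted p of 0.0509 to 0.626). Perp lost its call without episomal iHep 1 or 2 or viral iHep 2 or hepatocyte 2 (adjusted p of 0.0735 to 0.39). The bile acid list lost the call without episomal iHep 1 or viral iHep 2 or hepatocyte 3 (adjusted p of 0.0658, 0.141 and 0.191), the p53 list without episomal iHep 2 or hepatocyte 3 (0.134 and 0.191), the cell cycle list without viral iHep 1 (0.984) and the xenobiotic and acute phase lists without viral iHep 2 or hepatocyte 3 (0.133 to 0.264). The bile duct list gained a call without episomal iHep 2 or viral iHep 1 (adjusted p of 0.0277 and 0.0114), the glycolysis list without episomal iHep 2 (0.00113), the liver transcription factors, epithelial and positional lists without viral iHep 1 (0.0113, 9.64e-06 and 4.52e-05) and the YAP list without viral iHep 2 (1.49e-09). For p53 and senescence genes the direction of camera's test turned without viral iHep 1 (median 0.20, adjusted p = 0.0606). For epithelial genes the direction of camera's test turned without viral iHep 2 (median -0.12, adjusted p = 0.000473). Quantile and loess normalization ended the call of the xenobiotic, bile acid, acute phase and p53 lists (adjusted p of 0.117 to 0.168). Averaging probe sets added a call of the bile duct and glycolysis lists (adjusted p of 0.0128 to 0.0388). A fit of these groups alone ended the call of the xenobiotic, bile acid, acute phase and p53 lists (adjusted p of 0.0909 to 0.143). Leaving out both hepatocyte 3 and viral iHep 2 ended the call of the xenobiotic, bile acid and acute phase lists (adjusted p of 0.19 to 0.577), added the YAP list (2.36e-06) and called the epithelial list lower (0.0162).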

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

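The splits of the arrays and camera's list tests were planned, and the other tests in this part were chosen after the results were seen. Of the 35 ways to split the 7 iHep and hepatocyte arrays into 4 and 3, 1 gave as many genes as the real one, itself. It gave 1989 genes in a fit of these arrays as 2 groups, against at most 116 in the others. That share, 1 in 35, is under 0.05 and is the smallest that these splits allow. It speaks only against an arbitrary grouping of the arrays. The real split also follows the distribution sets, so the splits cannot tell the cell types from the sets.

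Episomal and viral iHeps differed in 6 gene lists by camera's test of the difference: plasma proteins (adjusted p = 1.75e-10), xenobiotic enzymes (0.00935), bile acid and transporter genes (0.0221), cell cycle genes (0.000278), acute phase and inflammatory genes (0.00756), and p53 and senescence genes (0.0162). With an estimated correlation the adjusted p was 0.996 for each, and only the call of plasma proteins held when each array was left out; the others were lost without hepatocyte 3 (0.133, 0.191, 0.191 and 0.191 for xenobiotic, bile acid, acute phase and p53 genes) or without viral iHep 1 (0.984 for cell cycle genes), some of them without other arrays too. The xenobiotic, bile acid, acute phase and p53 calls were also lost after quantile and loess normalization (0.117 to 0.168). Of 15588 unnamed probe sets, outside the main measurement, 13 rose and 2 fell in episomal against viral iHeps. Against the MEF array 118 and 67 rose and 158 and 140 fell in episomal and viral iHeps.

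Xist was 10.52 and 10.47 in viral iHeps and 5.66 and 5.57 in episomal iHeps, while the Y-linked genes Eif2s3y, Uty and Kdm5d were lower in viral iHeps by a median difference of -3.31. Eif2s3y was 3.08 and 2.91 in viral and 7.85 and 7.75 in episomal iHeps, and the MEF array had both Xist (8.11) and Eif2s3y (7.34). Loss of the Y chromosome in culture predicts no change in Xist, and the difference of 4.88 ± 0.303 (SE) argues against it. A candidate explanation is that the viral lines came from female and the episomal lines from male embryos, and the high Xist and low Y-linked values this needs are there. Embryo sex then differs together with the vector, and which of them goes with any other difference between these iHeps cannot be separated in this design.

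Viral iHeps 1 and 2 differed at least 2-fold in 1648 genes, as in Trf (3.70 and 11.61). Unequal scaling is argued against, since 1587 genes stayed 2-fold apart after quantile normalization. MEFs left in viral iHep 2 are argued against by 99 genes high in MEFs, which lay 5.86 below the MEF array there (median, quartiles 5.26 to 6.66). A swap is argued against by its highest correlation with another group, 0.945, below the 0.995 of close replicates. Both viral arrays lay closer to episomal ones (0.9435 to 0.9668) than to each other (0.9338). Separately picked lines, or an outside sample, may account for the gap and were not tested.

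Hepatocyte 3 differed from hepatocytes 1 and 2 at least 2-fold in 1210 genes after quantile normalization, against 25 between those 2. Normalization took the median absolute difference from 0.714 as deposited to 0.27, so the scaling accounts for much of it, but is argued against as the whole cause, since hepatocytes 1 and 2 differ by 0.0795. Cells of another type cannot be told apart: over 89 macrophage, endothelial, stellate, mesothelial and blood cell genes the median difference was -0.0959 (95% bootstrap interval -0.199 to -0.0236 over 2000 draws), but only 14 of them lie at or above the median level in hepatocytes, of which 5 were higher and 9 lower in hepatocyte 3, as in Cd3e (0.28), Cd14 (-1.39) and Ecm1 (-3.25). No biological explanation was tested. Another mouse or another state of the culture may lie behind it, with Cyp1a1 (4.58), Cyp3a11 (3.13) and Ifi202b (-5.21) among the largest differences.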

How the results depend on the processing

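The set block, the fit within 1 set and omitting both arrays that stand apart were chosen after seeing the data, the other settings before. Comparisons are given in the order episomal iHeps, viral iHeps and hepatocytes against the MEF array, then episomal iHeps, viral iHeps and all iHeps against hepatocytes, then episomal against viral iHeps. The intensity trend, the mean of all probe sets and the added 2-fold threshold kept all 7 counts of genes within 1.5 times; the filter at the median level moved 1 of them (392 genes for viral iHeps against the MEF array), and quantile and loess normalization kept only that of episomal against viral iHeps. Quantile normalization gave 2254, 1695, 1597, 2810, 2600 and 3878 genes in the first 6 comparisons, and loess 2166, 1604, 1530, 2737, 2523 and 3763. Both bring hepatocyte 3 to the level of the other arrays, and whether that is the cause was not tested. With only the compared groups in the fit, the counts that moved were 7194 for episomal iHeps against the MEF array, 0 for viral iHeps against it (limma, 3211 genes at an unadjusted p under 0.05), 521 for viral iHeps against hepatocytes and 21 for episomal against viral iHeps; fewer arrays set the spread there. Leaving out single replicates gave 411 to 4756, 424 to 4291, 527 to 2291, 267 to 5073, 506 to 5015, 686 to 6146 and 16 to 346 genes, with the highest count without hepatocyte 3 in the first 6 and without viral iHep 1 in the last. Replicate numbers do not pair the arrays: after group means were removed, arrays with the same number correlated at 0.033, -0.0349 and 0.0296. With the replicate number as a replicate block on the 6 numbered arrays, 3826, 3706, 5000 and 31 genes were called in the last 4 comparisons; that fit also leaves out hepatocyte 3. Where the set was a random block (correlation 0.927) the counts were 135, 130, 2663, 5, 9, 5 and 299. Within 1 set, hepatocytes against the MEF array gave 6174. Without hepatocyte 3 and viral iHep 2 they were 8536, 7552, 5448, 8838, 7533, 9227 and 2546. Fewer genes were called higher than lower in the first 6 comparisons. More were called higher without both arrays, without hepatocyte 3 (except for hepatocytes against the MEF array) and with the replicate block (2251 and 1575, 2114 and 1592, 2785 and 2215 for episomal, viral and all iHeps against hepatocytes). The same held for hepatocytes against the MEF array with the set block (1378 and 1285), within 1 set and with the filter (346 and 212), for episomal iHeps against it with the filter (442 and 293) and the groups alone, for episomal (514 and 497) and all iHeps (751 and 693) against hepatocytes with the filter, and for viral iHeps against them without viral iHep 2 (339 and 334). Between episomal and viral iHeps the balance turned to lower without viral iHep 2 (43 and 45) and without both arrays (1165 and 1381).

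The shares of hepatocyte-high genes higher in episomal iHeps were 44.46% after quantile normalization, 43.93% with the filter, 63.69% with the compared groups alone, 0.8708% with the set block and 68.3% without both arrays, and 24.68 to 61.94% leaving out single replicates. In viral iHeps they were 34.98% (quantile), 33.05% (loess), 0% (groups alone), 0.508% (set block), 65.97% (both left out) and 20 to 58.06%. Fibroblast-high genes lower in episomal iHeps made up 71.02% (loess), 57.08% (filter), 80.26% (mean of probe sets), 90.98% (groups alone), 8.794% (set block), 60.72% (both left out) and 66.44 to 80.41%. In viral iHeps the values were 62.07% (loess), 41.04% (filter), 0% (groups alone), 8.638% (set block), 53.71% (both left out) and 58.13 to 72.64%.

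Of the 168 list tests, 86 were called, 7 with an estimated correlation, 73 with quantile and 72 with loess normalization, 94 with the mean of probe sets, 82 with the compared groups alone, 76 without both arrays and 78 to 97 when single replicates were left out; with the filter 80 of 154 were called. The direction of camera's test turned for macrophage genes between hepatocytes and the MEF array with the filter (median -0.478). Between episomal and viral iHeps it turned for p53 and senescence genes without viral iHep 1 (median 0.2) and for epithelial genes without viral iHep 2 or without both arrays (-0.12 each); leaving out the other viral array gave medians of -1.446 and 0.246. Of the 642 values of named genes, 3 changed sign and passed the test there, all without both arrays: Klf4 in viral iHeps against the MEF array (0.373), Upk1b in viral iHeps against hepatocytes (-0.443) and Hnf4a in all iHeps against hepatocytes (0.225). The causes were not tested. Calls were lost for 132 and 131 named values without episomal iHep 1 or 2, for 69, 75 and 32 without hepatocyte 1, 2 or 3, for 29 and 48 without viral iHep 1 or 2, and for 335 with the set block. Of the named values called, 50 of 78, 49 of 61, 52 of 65, 40 of 82, 53 of 75, 70 of 88 and 7 of 24 held leaving out each replicate, and 49, 0, 50, 40, 50, 68 and 5 in all settings chosen before. The intensity trend and the 2-fold threshold have no list values, since camera uses neither, and single genes below the median level have none with the filter. The arrays carry no detection calls, so how far dim genes lie above background was not measured.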

Other observations

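The random lists in this part were all chosen as a test after the values were seen, and so were the genes named. The RNA Meg3, an imprinted gene (read from 1 parental copy), was 10.92 in the MEF array, 4.90 and 5.29 in the episomal arrays, 4.92 and 5.02 in the viral arrays and 5.98 ± 0.32 in hepatocytes. Rian, its neighbor in the same cluster, was 10.23 in the MEF array, 3.56 and 3.64 in the episomal and 3.47 and 3.68 in the viral arrays, and 4.97 ± 0.03 in hepatocytes. Paternally expressed Ndn was 9.48 in the MEF array, 3.21 ± 0.18 in episomal and 3.77 ± 0.83 in viral iHeps, and 6.63 ± 0.11 in hepatocytes. Peg3 stayed high in iHeps, at 11.39 ± 0.02 and 11.40 ± 0.12, next to 9.98 in the MEF array and 7.70 ± 0.84 in hepatocytes. Igf2 and Plagl1 were 11.37 and 10.25 in the MEF array and 11.29 and 11.36 in viral iHep 2, but 4.61 and 3.95 in viral iHep 1 and 6.94 ± 0.34 and 4.08 ± 0.04 in episomal iHeps. The positional gene Hoxa10 was 8.85 in the MEF array, 8.86 ± 0.17 in episomal iHeps, 8.31 and 6.87 in viral iHeps and 4.53 ± 0.24 in hepatocytes. The cell cycle inhibitor Cdkn2a was 7.13 in the MEF array, 9.26 ± 0.24 in episomal iHeps, 8.77 and 9.21 in viral iHeps 1 and 2, and 3.26 ± 0.28 in hepatocytes.

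Within the viral group the p53 and senescence genes lay lower in viral iHep 2 than in viral iHep 1, by a list median of -1.36, as in Eda2r (3.86 against 7.55), Phlda3 (6.42 against 9.50) and Ccng1 (8.20 against 11.21). YAP and TGF-beta targets differed by a median of -1.45 and epithelial genes by -0.81, while cell cycle genes lay higher in viral iHep 2 (median 0.50). The endoderm factor Sox17 was 10.32 in viral iHep 1 and 2.74 in viral iHep 2, and between 5.64 and 6.97 in episomal iHeps. Within the hepatocyte group, hepatocyte 3 lay lower after quantile normalization in interferon-stimulated genes (median -0.95), fetal liver and imprinted genes (-0.69), liver transcription factors (-0.44), bile duct (-0.43), fibroblast (-0.26), acute phase and inflammatory (-0.25), stellate and mesothelial (-0.25) and plasma protein genes (-0.17), with at most 1% of 10000 random lists of the same size lower. It lay higher in glucose (0.22), urea cycle and amino acid (0.21) and lipid genes (0.16), with at least 98.1% of random lists lower. Random lists ignore that genes of a list vary together, and 1 array stands on one side of each comparison within a group. The differences between the viral arrays were not tested.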
